A study of Mus musculus with 10 samples.

How the data were processed

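RNA was measured by sequencing in regulatory T (Treg) cells sorted from mouse spleen. The cells came from mixed bone-marrow chimeras, mice whose blood system was rebuilt from a mixture of equal parts of marrow marked by CD45.1 and marrow of the tested genotype. The sorted cells carried CD4, the Foxp3-YFP reporter and CD45.2 but not CD45.1, so they derived from the tested marrow. That marrow was Foxp3-Cre (WT) or Foxp3-Cre with loxP-flanked Flcn alleles (Flcn KO). The design text states 5 biological replicates per group, which gave 10 libraries. RNA was isolated with a column kit for small samples and cDNA was made by a NuGEN method for low RNA input, per the labels' protocols. No batch, sex, or date of collection or sequencing was given in the sources used here. The sample codes number all WT libraries before all Flcn KO libraries. An effect of such an order, if any, cannot be told apart from genotype.

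The deposited table held 14738 genes, and its lowest mean over the 10 libraries was 2.02 normalized counts. Each library had a column of signal, headed by a sample code. The signal is read here as normalized counts, that is gene read counts divided by 1 size factor per library. That reading rests on the whole multiples and recomputed size factors given below. The authors' mean column is the mean of these 10 signal columns. The deposited table also gave the authors' own comparison as a log2 fold change with its standard error, a Wald statistic (a score) and a p-value with its adjusted value. Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.3a, RSEM 1.3.1 and DESeq2 1.24.0, with mm9 as the genome build, and the notes give them no role or order. The gene annotation, the read filters and the rule by which genes entered the table are not given in the sources used here. The gene models at hand are of another build than mm9, so no coordinates are printed.

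Every column could be turned back into whole reads. All values, 100% in each library, were whole multiples of what 1 read was worth, within 0.01 reads, and 1 read was worth 0.628 to 1.27 normalized counts. Size factors recomputed with DESeq2 from these reads differed from those behind the deposited values by at most 0.0194%. The reads of the table summed to 1914516 to 4153854 per library, and 12732 genes had reads in all 10 libraries. These sums cover the genes of the table alone. A count of 3 reads, the limit that a count of 0 allows, corresponds to between 7.22e-05% and 0.000157% of a library's reads. Intervals and such limits cover counting error only, because reads without molecular identifiers are not independent molecules. Pairs of libraries of 1 group differed by more than counting noise, with a chi-square per degree of freedom of 2.24 to 35.0, so none was counted as a repeat of another. The larger values, 27.9 and above, all involved WT replicate 1.

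Because the deposited values were normalized and not raw counts, the main test was limma on log2(normalized count + 1), as laid down before the data were examined for values of this kind. Genes with a normalized count of 1 or more in at least 5 libraries were tested (14723 genes). The model held genotype alone, moderated variances came from eBayes without trend or robust settings, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are therefore on the log2(normalized count + 1) scale, where the added 1 shrinks differences between low counts. For genes with few reads they are not lower bounds. Beside the authors' log2 fold changes they could be smaller, as for Dapl1 (1.81 against 2.86). They could also be larger in size, as for Klrg1 (-2.49 against -2.12). Flcn was also compared by an exact two-sided permutation test over all 252 splits of the libraries. Means are given with the SD over 5 libraries.

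Gene lists, 31 in number with 710 entries, were fixed before the data were examined, and 642 entries matched a gene of the table (2 of them through another symbol). Lists with at least 5 tested members entered limma's camera with a preset inter-gene correlation of 0.01. The same test with a correlation estimated per list, and fry, a rotation test of whether a list's genes move on balance one way, were alternatives. For each list the members past the threshold were counted over all tested genes and adjusted over the list alone. Of the table's symbols, 12894 matched the RefSeq gene table of assembly GRCm38.p6 or its synonyms. That table served for names and for which genes neighbour each other, and transcript lengths and GC contents came from the GENCODE vM21 transcripts.

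Genes named in the text follow a rule fixed before the data were examined. It takes Flcn; the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap and whose mean in the higher group lay above the median of tested genes; up to 4 members past the threshold per list, by smallest p; and a fixed panel of Treg, lysosomal and mitochondrial genes. Antigen receptor segments and clone or model names were left out of the largest changes. Ppargc1a of the panel is not analysed here. Other genes are named where this is said.

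Alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter and a stricter one (5 or more in 5 libraries), median centring and quantile normalization, limma with trend and robust on or with array weights, the replicate number as a block, the authors' comparison, and leaving out each library. Fits on the recovered whole reads were added after the data were seen: edgeR's quasi-likelihood test with several scalings, DESeq2 and limma-voom. So were the gene lists with the stricter filter and without Flcn. Upper-quartile scaling and count filters, foreseen for raw counts, were not run.

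The test was tested on simulated data drawn for the real genes at the real depths, with 200 genes changed. Reads followed edgeR's count model with its trended dispersion, a spread set by a gene's level alone. All libraries shared that spread, so no outlying library such as WT replicate 1 was drawn. Genes with the lowest means were not among those changed. For the Flcn KO and WT comparison, limma over 14716 genes recovered 2.99% of 67 genes changed 1.5-fold, 22.4% of 67 changed 2-fold and 78.8% of 66 changed 4-fold, and 3 of its 72 calls were unchanged genes. On the same simulated reads edgeR, over 10462 genes, recovered 26.9%, 64.2% and 84.8%, with 7 unchanged genes among 124 calls. Calculations used R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.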

Results

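Gene expression was profiled in splenic Treg cells, the Foxp3-expressing CD4 T cells that restrain immune responses, from mixed bone-marrow chimeras. The tested marrow was either WT or lacked Flcn in Foxp3-expressing cells by design. Flcn encodes folliculin, a lysosome-associated protein that acts on the Rag GTPases of the nutrient-sensing pathway. The comparison asks how the loss of folliculin changes Treg expression in mice that also hold normal Treg cells. There were 5 libraries per group, and the table's genes held 1914516 to 4153854 reads per library. Mitochondrial rRNA took 24.7% to 31.8% of these reads in 9 libraries and 44.1% in WT replicate 1 (95% Wilson interval 44.1 to 44.2; every library's interval reached at most 0.0611 points to either side). The group means did not differ past an exact two-sided permutation test in total reads (p = 0.429), in mitochondrial rRNA share (p = 0.984) or in the number of genes at 0 (p = 0.675), with n = 5 per group. For mitochondrial rRNA, WT replicate 1 raised the WT mean. The other WT libraries had 24.7% to 26.6%. Flcn KO replicates 1, 2, 3 and 5 had 28.2% to 31.8%, above all of these, and Flcn KO replicate 4 had 24.8%. The test of means therefore does not show that the groups were matched in this share.

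In the libraries labelled Flcn KO, 4 of 15 genes of the folliculin circuit, Flcn among them, and 9 of 49 lysosomal genes rose, and 9 of 34 genes of effector Treg cells fell, with none of these lists' members called the other way (limma, adjusted p under 0.05 over all tested genes). Flcn itself was higher in the libraries labelled Flcn KO. Its mean was 54.2 ± 13.8 normalized counts in WT and 138 ± 14.4 in the libraries labelled Flcn KO (SD, n = 5 each). The fitted log2 fold change was 1.36, that is 2.56-fold on the log2(normalized count + 1) scale (SE 0.17, limma adjusted p = 0.00476). Every library labelled Flcn KO (124 to 158) lay above every WT library (45.6 to 78.0), which is the strongest separation that an exact permutation test can give (p = 0.00794, two-sided). These values rest on 41 to 64 reads per WT library and 116 to 198 reads per library labelled Flcn KO. Values per gene do not show whether reads fell in the deleted part of the transcript, so Flcn does not check the labels, and each direction below is that of the labels.

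In the list of the folliculin complex and MiT/TFE factors, 3 of the 14 tested members other than Flcn rose and none fell over all tested genes, and 5 rose adjusted over the list alone (4 and 6 of 15 with Flcn). Rragd, a Rag GTPase that folliculin acts on, rose from 40.4 ± 8.92 to 223 ± 10.4 normalized counts (log2 fold change 2.46, SE 0.15, adjusted p = 4.18e-05). Both folliculin-interacting proteins rose, Fnip1 from 176 ± 26.5 to 402 ± 74.5 (1.18, SE 0.17, adjusted p = 0.0103) and Fnip2 from 8.16 ± 3.42 to 30.3 ± 8.87 (1.79, SE 0.28, adjusted p = 0.0132). The transcription factors that the complex controls did not pass the test: the log2 fold change was -0.48 (SE 0.29, adjusted p = 0.523) for Tfeb and -0.05 (SE 0.42, adjusted p = 0.974) for Tfe3. Without Flcn the list's median log2 fold change was 0.43, and 5 of the 14 members had a negative one (camera adjusted p = 8.33e-05; adjusted p = 0.0173 with an estimated correlation). With Flcn the median was 0.58 (camera adjusted p = 4.01e-06; adjusted p = 0.0173 with an estimated correlation).

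**Figure D1:**
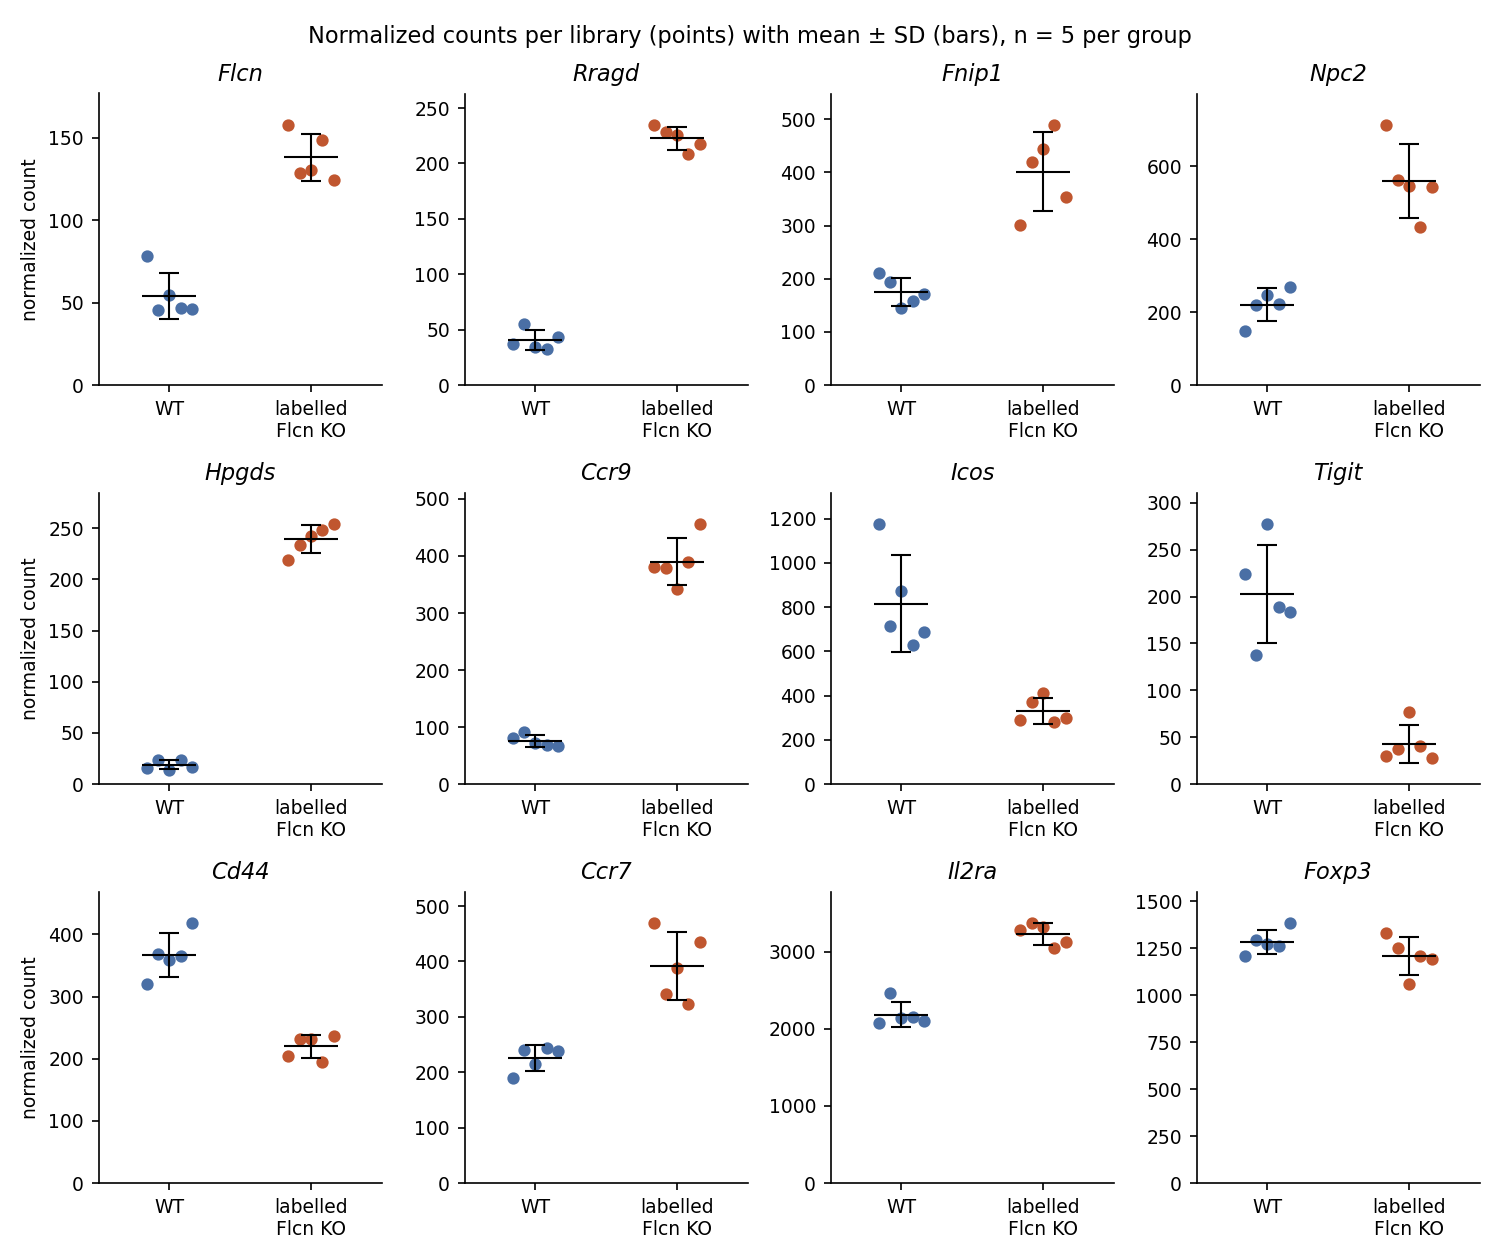
Normalized counts (vertical axes, starting at 0) of 12 genes in the 5 WT libraries and the 5 libraries labelled Flcn KO; points are libraries, the long bar is the mean and the whisker the SD. Flcn, Rragd, Fnip1, Npc2, Hpgds, Ccr9, Ccr7 and Il2ra were higher and Icos, Tigit and Cd44 lower in the libraries labelled Flcn KO, without overlap of the groups, while Foxp3 was 1283 ± 64.1 in WT and 1207 ± 99.97 in the libraries labelled Flcn KO (n = 5 each).

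Lysosomal genes were higher in the libraries labelled Flcn KO. Of 49 tested lysosomal hydrolases and membrane proteins, 9 rose and none fell, and 19 rose adjusted over the list alone. Gaa, the lysosomal enzyme that breaks down glycogen, rose from 19.5 ± 6.03 to 62.1 ± 12.1 normalized counts (log2 fold change 1.65, SE 0.22, adjusted p = 0.00657). Npc2, which carries cholesterol in the lysosome, rose from 221 ± 45.6 to 559 ± 100.4 (1.35, SE 0.19, adjusted p = 0.00974). The peptidase Tpp1 rose by 1.13 (SE 0.17, adjusted p = 0.0115). The list's median was 0.43, 42 of its members had a positive log2 fold change, and camera's adjusted p was 5.3e-13 (adjusted p = 0.0173 with an estimated correlation). Among 18 subunits and accessory proteins of the vacuolar ATPase, the proton pump of the lysosome, 1 rose over all tested genes and 13 rose adjusted over the list alone. That member, Atp6ap2, went from 62.3 ± 9.92 to 134 ± 13.8 (adjusted p = 0.00578), and the list's median was 0.57 (camera adjusted p = 5.07e-10; adjusted p = 0.0173 with an estimated correlation). Markers of myeloid and dendritic cells, which are rich in lysosomes, had a median of 0.40 in the same direction, with none of 18 past the threshold on either count (camera adjusted p = 0.0523; adjusted p = 0.752 with an estimated correlation). The myeloid list's camera adjusted p ran from 0.00272 without WT replicate 2 to 0.598 without WT replicate 1. B-cell markers had a median of 0.47.

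The other lists tied to the lysosome and to mitochondria showed few changes. In the autophagy list 1 of 32 members, Gabarap, rose (0.89, SE 0.13, adjusted p = 0.0125), also adjusted over the list alone, and the median was 0.003 (camera adjusted p = 0.601). In the list of mitochondrial dynamics, biogenesis and mitophagy 1 of 21, the coactivator Ppargc1b, rose on both counts, from 22.8 ± 6.72 to 56.1 ± 7.50 (adjusted p = 0.0163). This list's median was -0.02 while its mean was 0.06 and camera's direction was up (camera adjusted p = 0.856). Opa1, which fuses inner mitochondrial membranes, had a log2 fold change of -0.14 (SE 0.11, adjusted p = 0.638). None of 46 oxidative phosphorylation genes passed on either count. Their median was 0.16 with a camera adjusted p of 0.00445, which was not kept with an estimated correlation (adjusted p = 0.618). None of 17 TCA cycle genes (median 0.14, camera adjusted p = 0.127) and none of 21 glycolysis genes (median 0.22, camera adjusted p = 0.341) passed on either count.

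Genes of effector Treg cells, the activated and tissue-homing form, were lower in the libraries labelled Flcn KO. Of 34 tested members 9 fell and none rose, and 20 fell adjusted over the list alone. The costimulatory receptor Icos fell from 816 ± 221 to 330 ± 57.7 normalized counts (log2 fold change -1.28, SE 0.20, adjusted p = 0.0127), and the activation marker Cd44 from 366 ± 35.4 to 220 ± 18.8 (-0.73, SE 0.12, adjusted p = 0.0167). Ccr2, a receptor for inflammatory chemokines, fell from 216 ± 46.9 to 69.3 ± 23.6 (-1.66, SE 0.25, adjusted p = 0.0118). S100a4 had a log2 fold change of -2.21 (SE 0.31, adjusted p = 0.00962) and Prdm1, which encodes Blimp-1, of -1.16 (SE 0.23, adjusted p = 0.037). Klrg1, a marker of terminal effector cells, was 48.6 ± 22.8 in WT and 11.3 ± 13.8 in the libraries labelled Flcn KO, and did not pass (-2.49, SE 0.64, adjusted p = 0.102). Of the fits with 1 library left out, only that without Flcn KO replicate 3 called Klrg1 (-3.03, adjusted p = 0.0238). Klrg1 also passed with a pseudocount of 5, with trend and robust on, in edgeR and in limma-voom. It did not pass in DESeq2 or in the authors' comparison (adjusted p = 0.0742). Il10 differed by less than its standard error (-0.09, SE 0.37, adjusted p = 0.946). The list's median was -0.72 (camera adjusted p = 4.97e-16), and 31 members had a negative log2 fold change. The list did not keep its call with an estimated correlation (adjusted p = 0.0573) but kept it in fry (adjusted p = 0.00203). Over the same libraries the median of B-cell markers was 0.47, in the other direction.

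Genes of resting or central Treg cells moved the other way in part. Of 22 tested members 3 rose and none fell, and 7 rose adjusted over the list alone. The lymph node homing receptor Ccr7 rose from 226 ± 23.1 to 391 ± 61.5 (0.79, SE 0.14, adjusted p = 0.0258) and the interleukin-6 receptor gene Il6ra rose by 0.73 (SE 0.15, adjusted p = 0.0395). The third, Dapl1, had 0.495 ± 0.69 normalized counts in WT and 4.21 ± 1.90 in the libraries labelled Flcn KO (adjusted p = 0.0482), rests on few reads, and was not called in the authors' comparison (adjusted p = 0.154). With 1 library left out, Ccr7 lost its call in 8 of 10 fits, Il6ra in 9 and Dapl1 in 8. Tcf7 did not pass (0.38, SE 0.11, adjusted p = 0.156). The list's median was 0.18 (camera adjusted p = 0.000358). The list lost its call with an estimated correlation (adjusted p = 0.242) and kept it in fry (adjusted p = 0.0033). B-cell markers, with a median of 0.47, lay in the same direction.

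The Treg core list was split. Of 20 members 3 rose and 3 fell, and adjusted over the list alone 3 rose and 7 fell. The inhibitory receptor Tigit fell from 202 ± 52.1 to 42.7 ± 20.1 (-2.28, SE 0.29, adjusted p = 0.00476) and the transcription factor Ikzf2 changed by -0.55 (SE 0.11, adjusted p = 0.0336). The integrin gene Itgae rose from 475 ± 74.2 to 958 ± 125 (1.01, SE 0.15, adjusted p = 0.0118), Socs2 rose by 0.81 (SE 0.14, adjusted p = 0.0231), and Il2ra, the high-affinity receptor chain for interleukin-2, rose by 0.56 (SE 0.11, adjusted p = 0.0292). Foxp3 had a log2 fold change of -0.09 (SE 0.11, adjusted p = 0.79), and Ctla4 of -0.52 (SE 0.14, adjusted p = 0.106). The list's median was -0.22 (camera adjusted p = 0.0129; adjusted p = 0.458 with an estimated correlation). The T helper cytokines and regulators had a median of -0.47 (camera adjusted p = 0.00445). Their call was lost with an estimated correlation (adjusted p = 0.058) and kept in fry (adjusted p = 0.0033). Of 10 tested members 2 fell, 4 adjusted over the list alone. Those 2 were the chemokine receptor Ccr6 (-1.07, SE 0.17, adjusted p = 0.0158) and Ifng, with 20.7 ± 9.63 normalized counts in WT and 2.32 ± 2.53 in the libraries labelled Flcn KO (adjusted p = 0.0392). In the migration and adhesion list of 16 the gut-homing receptor Ccr9 rose from 76.1 ± 10.7 to 390 ± 41.4 (2.35, SE 0.14, adjusted p = 2.72e-05), while Cxcr6 (-1.15, SE 0.18, adjusted p = 0.0132) and Itga1 fell. Itga1 had 7.53 ± 3.69 normalized counts in WT and reads in 1 of the 5 libraries labelled Flcn KO (adjusted p = 0.0258). Adjusted over the list alone, 1 rose and 6 fell; the median was -0.34 (camera adjusted p = 0.0425; adjusted p = 0.367 with an estimated correlation). Cell cycle genes did not pass singly on either count (0 of 36; median -0.11, camera adjusted p = 0.307), and Mki67 had a log2 fold change of -0.85 (SE 0.26, adjusted p = 0.159).

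**Figure D2:**
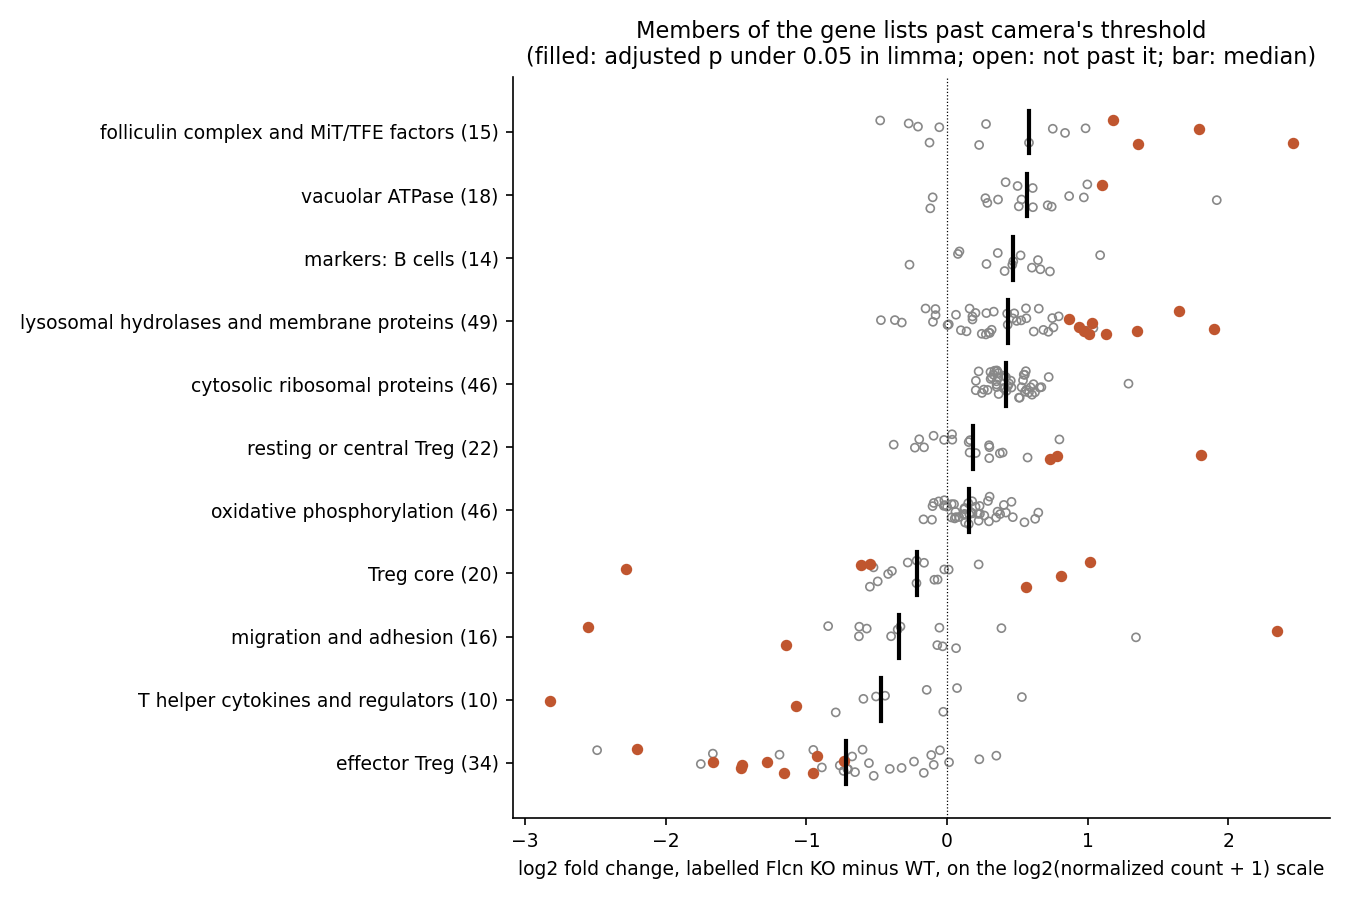
Log2 fold change (horizontal axis, libraries labelled Flcn KO minus WT, on the log2(normalized count + 1) scale) of each tested member of the 11 lists past camera's threshold with the preset correlation, with the number of members in brackets; filled points passed limma's adjusted p of 0.05, open points did not, and the black bar is the list's median. The medians run from 0.58 for the folliculin list to -0.72 for the effector Treg list, and the ribosomal, oxidative phosphorylation and B-cell marker lists have no filled point.

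The largest rise by the fixed rule was that of Ifit1bl2, from 3.10 ± 1.16 to 84.3 ± 13.6 normalized counts (log2 fold change 4.42, SE 0.23, adjusted p = 1.33e-05). It belongs to a family of closely related interferon-response genes, so the share of its reads that belongs to relatives is unknown and its value is uncertain. Hpgds, the prostaglandin D synthase of blood cells, rose from 18.8 ± 4.51 to 239 ± 13.9 (3.63, SE 0.16, adjusted p = 9.16e-06). Col27a1 (2.48), Rragd (2.46), the lipid flippase gene Atp8a2 (2.44), the sorting adaptor gene Gga2 (2.42), the enolase gene Eno2 (2.38), Ccr9 (2.35), the cation channel gene Trpm1 (2.34) and Bcl2l15 (2.18) followed, with adjusted p between 2.72e-05 and 0.0204. Among the falls Ttn, which encodes titin, had a log2 fold change of -3.06 (SE 0.43, adjusted p = 0.00974), from 1636 ± 565 to 226 ± 175. Hip1 (-3.00), the O-glycan branching enzyme gene Gcnt1 (-2.47), the metalloprotease gene Adam8 (-2.46), Tigit (-2.28), Arnt2 (-2.27), Nav2 (-2.16), Ttc39c (-2.14), the securin gene Pttg1 (-2.04) and the macrophage growth factor gene Csf1 (-1.88) had adjusted p between 0.000128 and 0.0368.

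Other lists moved little or held few or no single calls in limma's main fit. Of 34 interferon-stimulated genes 1, Cxcl10, fell on both counts (-1.57, SE 0.31, adjusted p = 0.0336; median -0.08, camera adjusted p = 0.412). Of 12 genes of the TGF-beta response 1, the integrin gene Itgb8, fell (-1.62, SE 0.25, adjusted p = 0.0127), with 1 up and 1 down adjusted over the list alone (median 0.18, camera adjusted p = 0.335). All 46 cytosolic ribosomal protein genes had a positive log2 fold change with a median of 0.42. In limma none passed over all tested genes and 23 rose adjusted over the list alone. In edgeR on the recovered reads, 25 of the 45 it tested rose over all its tested genes and 0 fell. The call (camera adjusted p = 1.2e-18) was lost with an estimated correlation (adjusted p = 0.316) and kept in fry (adjusted p = 0.035). No member passed over all tested genes among 12 hypoxia-inducible factor targets (median 0.03, camera adjusted p = 0.857), 28 genes of cholesterol and fatty acid synthesis (-0.01, mean 0.01, camera's direction up, 0.959), 18 of fatty acid oxidation (0.03, 0.959), 16 of the integrated stress response (0.07, 0.339), 19 of cell death (-0.03, 0.815), 20 of the antigen receptor response (-0.09, 0.532) and 19 immediate early and heat shock genes (-0.12, 0.318). Adjusted over the list alone, 1 hypoxia-inducible factor target rose and 1 fell, 2 stress response genes rose, and the others showed none.

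Markers of cells other than Treg cells were also measured. B-cell markers had a median log2 fold change of 0.47 over 14 tested genes, none of them past the threshold on either count (camera adjusted p = 0.00119; adjusted p = 0.457 with an estimated correlation). Their mean level on the log2(normalized count + 1) scale was 5.24 to 6.03 in Flcn KO replicates 1, 3, 4 and 5, above every WT library (4.62 to 5.19), and 4.77 in Flcn KO replicate 2. The list kept its call with the preset correlation without any 1 library (adjusted p at most 0.0179, without Flcn KO replicate 3). Of 8 conventional CD4 T cell markers Cd226 fell (-0.82, SE 0.17, adjusted p = 0.0437), with 2 up and 1 down adjusted over the list alone (median -0.05, camera's direction up, camera adjusted p = 0.959). Of 7 plasma cell markers Prdm1 fell, with 1 up and 1 down adjusted over the list alone (median 0.20, camera adjusted p = 0.618). The 8 markers of CD8 T and NK cells showed no call on either count (median -0.03, camera adjusted p = 0.959). Erythroid and platelet markers (3 tested) and stromal markers (1 tested) were too few for the test, and none passed over all tested genes, with 1 stromal marker lower adjusted over the list alone.

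**Figure D3:**
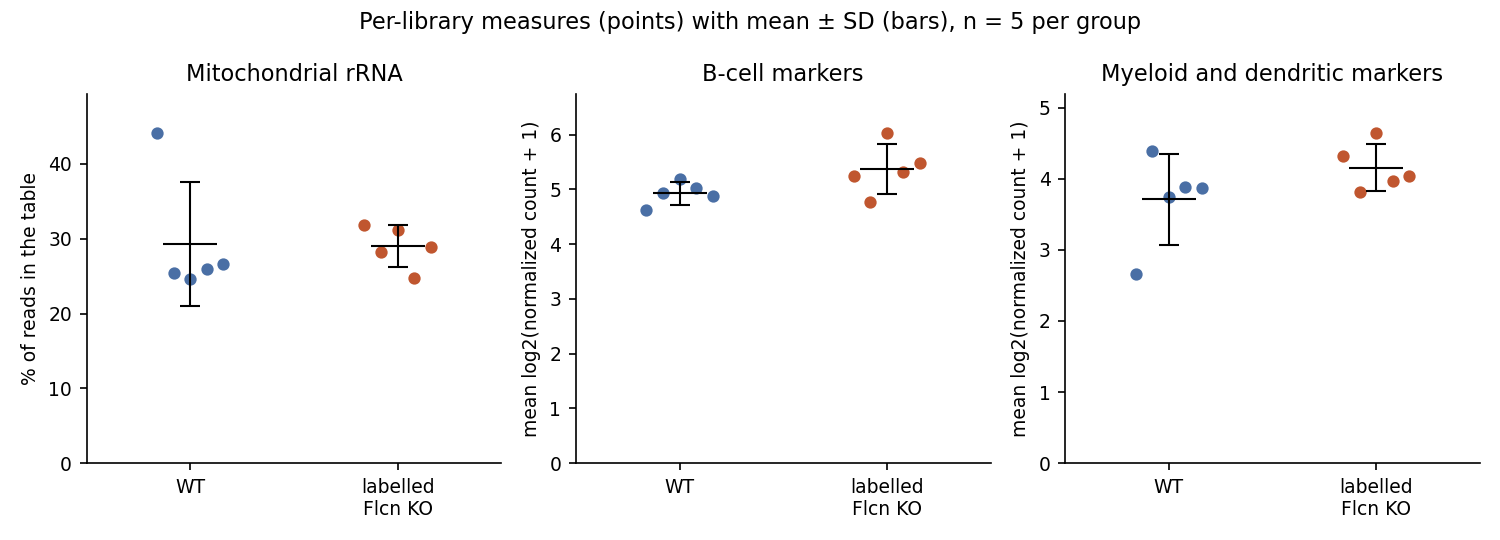
Share of mitochondrial rRNA in the table's reads (left axis, %), and mean level of B-cell markers (middle) and of myeloid and dendritic markers (right) on the log2(normalized count + 1) scale; points are the 5 WT libraries and the 5 libraries labelled Flcn KO, the long bar is the mean and the whisker the SD. WT replicate 1 had the highest share of mitochondrial rRNA (44.1%) and the lowest myeloid level (2.66), and Flcn KO replicate 3 had the highest levels of both marker sets (6.03 and 4.64).

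Across the transcriptome, limma called 252 of 14723 tested genes at an adjusted p under 0.05, 139 higher and 113 lower in the libraries labelled Flcn KO, of which 172 changed at least 2-fold. The groups did not overlap for 245 of these 252 genes, and for 4.92% of all tested genes against 0.794% by chance. Of the 252, 222 were also called in the authors' deposited table, which called 366 higher and 337 lower, and edgeR on the recovered reads, which tested 10493 genes and 192 of these 252, called 189 of them (317 higher and 275 lower in all), each in the same direction. In 99 other splits of the libraries into 5 and 5, camera with the preset correlation passed a median of 4 lists and up to 11. These splits mix the genotypes and can keep part of their difference, so they do not give the rate of false list calls. A list past that test alone is still read with caution. Leaving out 1 library left 72 to 134 genes higher and 44 to 87 lower (134 and 83 without WT replicate 1), and of 49 named genes past the threshold 15 lost their call without some library: Adam8, Ccr7, Cd226, Cxcl10, Dapl1, Eno2, Gga2, Hip1, Ifng, Ikzf2, Il2ra, Il6ra, Itga1, Prdm1 and Socs2.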

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

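The tests of a single wrong label, of swapped labels and of reads outside the deleted part were chosen after the result was seen; that of neighbouring genes was set down before. A library was singled out where its gap to the nearest of the other 4 of its group exceeded 0.71 of the group's range. Over 126 groups of 5 values, 9 met this, and chance gives about 1 in 20.

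The share of mitochondrial rRNA was 44.1% in WT replicate 1, against 24.7% to 26.6% in the other WT libraries. For Flcn, WT replicate 1 had 78.0 normalized counts against 45.6 to 54.7. For Il2ra, WT replicate 2 had 2457 normalized counts against 2070 to 2153. Among the libraries labelled Flcn KO, replicate 3 stood out in 3 genes: Tigit (77.4 against 27.6 to 40.6), Prdm1 (117 against 50.2 to 65.5) and Klrg1 (35.4 against 2.22 to 9.91). Flcn KO replicate 2 had 29.98 normalized counts of Arnt2 against 6.94 to 13.3. Flcn KO replicate 1 had 26.6 of Gga2 against 37.7 to 40.9, and 3.43 of Itga1 where the other 4 libraries had no reads.

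That Flcn was higher where it should be deleted was weighed further. A single wrong label is argued against: with 20 genes chosen on the other 9 libraries each time, a library lay nearer to the other group in at most 2 of them, and 0 libraries did so in most. A swap of all labels would put folliculin in the libraries labelled Flcn KO, and the lysosomal genes, which folliculin is known to restrain, would then be lower; their median was 0.43 higher, an argument that rests on this background. Reads from neighbouring genes are argued against by the nearest tested genes on both sides, Cops3 and 1700007J10Rik, whose log2 fold change was at most 0.22 in size. It stays open whether the 2.56-fold rise comes from a transcript without the deleted part, since values per gene hold no reads by exon.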

How the results depend on the processing

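The fits on recovered reads, the stricter filter for the lists (11 past, as with limma-voom) and the lists without Flcn (11 past) were chosen after the data were seen, and the other alternatives before. Against 139 genes higher and 113 lower, limma with trend and robust on gave 325 and 273, the authors' comparison gave 366 and 337, edgeR 317 and 275 (320 and 270 with DESeq2 size factors), DESeq2 379 and 348, limma-voom 305 and 284, and edgeR with WT replicate 1 left out 379 and 303. A pseudocount of 0.1 gave 72 lower genes; a pseudocount of 5, both filters, centring, quantile scaling and array weights kept both counts within 1.5 times. Within edgeR, scaling by library totals gave 164 and 138 where its own normalization gave 317 and 275. The median log2 fold change of all genes stayed within 0.01 of 0 under each scaling. The count of genes changed at least 2-fold (172) stayed within 1.5 times outside the replicate block and left-out libraries. In the simulated data limma also made fewer calls than edgeR (72 against 124) and recovered fewer 2-fold changes (22.4% against 64.2%). Those data followed edgeR's own count model, so the gap between the tools may differ in the real data. The cause of the shifts in the real data was not tested.

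Leaving out 1 library left 72 to 134 genes higher, 44 to 87 lower and 101 to 150 changed at least 2-fold, with fewer libraries in each fit. The higher count moved by over 1.5 times without WT replicate 3 (78), Flcn KO replicates 1 (88), 2 (72), 3 (88) or 5 (79). The lower count did so without WT replicates 2 (56), 3 (44), 4 (50) or 5 (50), or Flcn KO replicates 1 (58), 2 (54), 4 (68) or 5 (53), and the 2-fold count without WT replicate 3 (101) or Flcn KO replicates 1 (114), 2 (107) or 5 (113). Flcn passed in every setting. Il10 (-0.34 to 0.13) and Tfe3 (-0.41 to 0.18) crossed 0 when single libraries were left out and passed in none. Of 45 named calls that edgeR tested, it kept 45 and added Ctla4, Klrg1, Mki67 and Tcf7. Of all 49, a pseudocount of 0.1 lost 6 (Cd226, Cxcl10, Dapl1, Hip1, Ifng and Prdm1) and array weights 2 (Dapl1 and Ifng), while Dapl1 alone was lost with a pseudocount of 5, quantile scaling, trend and robust, DESeq2 and the authors' comparison (adjusted p = 0.154). The 15 named genes that lost their call without some library kept their direction; Gga2 lost it without Flcn KO replicate 2 (adjusted p = 0.0502), and the other 14 in 5 to 9 of the 10 fits, with a highest adjusted p of 0.12 (Dapl1). Klrg1 gained its call without Flcn KO replicate 3 (0.0238), and its adjusted p was 0.104 to 0.206 when any other library was left out.

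Replicate numbers did not pair the libraries. On a measure across genes that is not the correlation of the expression levels themselves, same-numbered libraries correlated at 0.0092 to 0.0325. On that measure none correlated best with its own number. With the replicate block, limma gave 35 higher, 24 lower and 59 changed at least 2-fold, and edgeR with the replicate block 283 and 256. Of the 49 named calls, limma with the block lost 31, among them Fnip1, Gaa, Npc2, Tpp1, Icos, Cd44 and Itgae, and edgeR with the block kept the 45 it tested; 11 lists passed with the block as without.

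Of the 11 lists past camera's preset correlation, 3 passed with an estimated correlation (folliculin, lysosomal and vacuolar ATPase) and 7 in fry, which also called the TCA cycle. Without the genes of other cell types 10 passed, and without single libraries 10 to 12. Migration and adhesion lost its call without WT replicate 3 (adjusted p = 0.0748) or 5 (0.103) or Flcn KO replicate 2 (0.0747), 4 (0.125) or 5 (0.105), oxidative phosphorylation without Flcn KO replicate 1 (0.118) and the Treg core without Flcn KO replicate 4 (0.0681). Myeloid and dendritic markers (0.0523) gained a call without WT replicate 2 (0.00272) or Flcn KO replicate 2 (0.023), 4 (0.0368) or 5 (0.0395), as did immediate early and heat shock genes without Flcn KO replicate 1 (0.0311). Upper-quartile scaling and count filters, meant for raw counts, were not run. At these depths the simulated limma test recovered 22.4% of 2-fold changes, so a gene not past the threshold is not shown to be unchanged.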

Other observations

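Genes in the next paragraph were chosen after their values were seen, and so were the tests of dilution by other cells and of fewer effector cells; the remaining tests were set down before.

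Several called genes lie next to each other. The interleukin-33 receptor gene Il1rl1 (-1.47, SE 0.28, adjusted p = 0.0327) and both interleukin-18 receptor genes, Il18r1 (-1.11, SE 0.21, adjusted p = 0.0287) and Il18rap (-1.78, SE 0.30, adjusted p = 0.0172), fell in limma's test. Il18r1 went from 607 ± 162 to 277 ± 49.7 normalized counts (SD, n = 5). The chemokine receptor genes Ccr2, Ccr3 (-1.98, SE 0.38, adjusted p = 0.0305) and Cxcr6 fell, while Ccr9, Ccr7 and Lztfl1, the neighbour of Ccr9, rose; for Lztfl1 the log2 fold change was 1.32 (adjusted p = 0.000841). The integrin genes Itga1 and Itga2 (-2.08, SE 0.39, adjusted p = 0.0293) fell while Itga6 rose from 594 ± 61.9 to 1088 ± 111 (0.87, SE 0.13, adjusted p = 0.0118). Grn (1.28, SE 0.19, adjusted p = 0.0112) and Galc (1.29, SE 0.24, adjusted p = 0.0299), which are in no list, rose. Of the lysosomal list, Lamp1 (1.01, adjusted p = 0.0176), Lamp2 (1.03, adjusted p = 0.0127) and Ctsl (1.90, adjusted p = 0.0129) rose.

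The rise of lysosomal and vacuolar ATPase genes was weighed against 3 technical explanations. Transcript length is argued against, since with each library's length trend removed the lists' medians were 0.45 and 0.54. A GC content trend is argued against by medians of 0.35 and 0.56 after its removal. Myeloid cells in the sort, which took CD4 and Foxp3-YFP cells, stay open. With the libraries' level of myeloid markers, 0 of which another list holds, as a covariate, the medians were 0.37 and 0.53. That level is a mean over markers with few reads (median 10.9 normalized counts in WT). It was 2.66 in WT replicate 1 against 3.74 to 4.40 in the other WT libraries. Such a covariate can correct too little, so this test cannot decide. B-cell markers were not tried as a covariate. The 18 myeloid markers had a median of 0.40 in the direction of the rise. The most abundant of them, Lyz2, Vcam1 and Mpeg1, had log2 fold changes of 0.14, -0.28 and 0.43, none past the threshold, and no biological explanation was tested.

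The fall of effector Treg genes is argued not to come from transcript length (median -0.72 after correction). The sort took CD4 and Foxp3-YFP cells, yet B-cell markers had a median of 0.47. None of 14 passed on either count, and the list's camera call (adjusted p = 0.00119) was lost with an estimated correlation (adjusted p = 0.457). Ighm was 1142 ± 91.0 in WT and 1518 ± 499 in the libraries labelled Flcn KO. RNA of other cells would lower all Treg genes alike. The effector median minus that of the Treg core was -0.50. Of all 252 splits of the libraries 2, the real split among them, gave as low a value (one-sided exact permutation p = 0.00794). The lowest value, -0.57, came from a split that mixes the genotypes. The low rank of the real split argues against RNA of other cells as the whole cause. Fewer effector cells and lower levels per cell cannot be told apart at a median of -0.72, because the libraries are bulk.

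Chromosome order gave another pattern. In the order of assembly GRCm38.p6, 16 adjacent pairs of tested genes were called in the same direction, against a median of 2 and a 95% limit of 5 over 10000 permutations (one-sided p = 1e-04, the smallest they can give). Pairs included Il1rl1 and Il18r1, Ccr2 and Ccr3, Itga1 and Itga2, Lztfl1 and Ccr9, and Abcb1a and Abcb1b. Shared regulation or reads of adjacent or related genes may underlie this, and the test does not separate them. Near Flcn, 5 of 200 genes were called (2.5%; Fnip1, Smcr8, Trim16, Fbxw10 and 2810021J22Rik) against 1.82% of 12670 elsewhere (one-sided Fisher's exact p = 0.302), so DNA of another strain around the targeted allele may or may not add calls there, and 5 calls are too few to decide.

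Chance is argued against for the counts of genes. It is not excluded, since 100 splits set a floor on the share and every other split mixes both genotypes. Of 100 splits of the 10 libraries into 5 and 5, drawn with the real one included, 1 gave as many genes higher (139; highest other 1), 1 as many lower (113; highest other 1) and 1 as many changed at least 2-fold (172; highest other 1). For the lists past camera's preset correlation, 2 splits gave as many (11; highest other 11), a share under 0.05. The other 99 splits passed a median of 4 lists and 83 of them at least 1. Such splits can keep part of the genotype difference, so they do not give the rate of false list calls. A list past that test alone is still read with caution. An estimated correlation kept 3 lists; other splits were not run with it.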
